A study of Mus musculus with 6 samples.

How the data were processed

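Messenger RNA was sequenced from haematopoietic stem and progenitor cells (HSPCs) of aged C57BL/6 mice in 6 libraries, 3 from cells treated with vehicle and 3 from cells treated with uridine. Per the labels' protocols, RNA of cultured cells was extracted with Trizol, mRNA was captured with poly-T beads, and paired reads of 150 bases were generated on a NovaSeq instrument. The authors deposited whole-number read counts per gene for the 6 libraries in a single table, which also gives each gene's position, biotype and length in bases. HISAT2 2.0.5 and the genome build mm10 are named, per the submitters' processing notes. The program that counted reads over genes, the annotation release, the strand setting and the treatment of reads with several best positions are not given in the sources used here. Of 54532 genes in the table, 54495 identifiers were found in GENCODE vM21, which is built on the same assembly, and 53585 of these (98.3%) had the same start and end.

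The deposited counts were used as they stand, and each column was assigned to its library by the sample name in the labels. Totals ran from 16109265 to 18638627 counts per library. At this depth a count of 3 corresponds to 0.161 to 0.186 CPM (counts scaled to a common library total), which covers counting error only. CPM values in the text are scaled by the normalization factors and are means ± SD over 3 libraries. Genes with too few counts were removed with filterByExpr at its default settings, which left 14706 genes, 12272 of them protein-coding. Libraries were normalized with TMM factors, and uridine was compared with vehicle by edgeR's quasi-likelihood F test (edgeR 4.0.16, glmQLFit with robust estimation, R 4.3.3) with treatment as the model's single term. Every adjusted p of a gene is from this test with Benjamini-Hochberg adjustment over the 14706 genes unless another test is named, and a gene was called changed at an adjusted p under 0.05. Fold changes are log2 values of uridine over vehicle ± SE, with the SE taken as the coefficient divided by the square root of the F statistic.

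Before the data were examined, 40 gene lists with 1254 different symbols were fixed from textbook knowledge; 1240 of the symbols occur in the table. They cover blood lineages and stem cell genes, nucleotide and energy metabolism, the ribosome, the cell cycle, stress responses, inflammation and signs of RNA quality. Each list was tested with limma's camera (limma 3.58.1, inter-gene correlation 0.01) on log2 CPM with a prior count of 2, which compares the list with all other tested genes, and p-values were adjusted over the 40 lists. For each list, called members were also counted with adjustment over the list alone. The genes to be named were fixed by a rule at the same time. They are the 8 largest rises and the 8 largest falls among protein-coding genes with adjusted p under 0.05, mean log2 CPM of at least 1 and no overlap between the groups, the 4 smallest p-values in each direction, up to 4 smallest p-values in each list, and 13 genes chosen in advance: Uck1, Uck2, Upp1, Cda, Slc29a1, Slc29a2, Slc29a3, Procr, Kit, Ly6a, Cd34, Cdkn1a and Cdkn2a. Predicted genes and pseudogenes were counted and not named. Any other gene in the text was chosen after its values were seen, and the text says so.

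The test was tried on simulated counts with the real means and library sizes, in which 50 genes at each of 4 folds were changed and 14455 were tested. The changed genes were drawn from those with a mean above 50 counts, so recovery at lower counts was not measured. Far fewer genes were changed than were called in the real data. The test recovered 18% of the 50 genes changed 1.1-fold, 76% of those changed 1.25-fold, 84% of those changed 1.5-fold and 96% of those changed 2-fold. Of its 146 calls, 9 were genes that had not been changed. In the same simulated counts, where no list was shifted, 1 list was called, and a list raised 1.25-fold in another simulation was called with no other. Genes were simulated independently of each other, so this does not cover lists whose genes vary together. Library pairs within a group differed by 2.28 to 2.52 chi-square units per gene, above the value of 1 that sampling alone would give, so no pair was treated as 1 library deposited under 2 names. No label says whether replicates came from separate cultures or mice, so the p-values measure only the spread between these samples, which may be technical. The coefficient of variation common to all genes, beyond counting error, was 3.42%.

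The alternatives were DESeq2 size factors, DESeq2's Wald test (DESeq2 1.42.0), limma-voom, 2 other count filters, a test against a 1.5-fold change, the replicate number as a block with and without a correction for gene length, protein-coding genes without mitochondrial ones, and each library left out in turn. For the lists they also included a correlation estimated per list and fry. A correction for gene length alone, one for gene length and GC content, and scaling by library size alone were added after the data had been seen. Reads from near-identical copies, such as ribosomal protein pseudogenes or nuclear copies of mitochondrial genes, may be split differently by the authors' counting, and without a stated strand setting reads of a gene are not separated from those of an overlapping antisense gene. Figures were drawn with matplotlib 3.10.9.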

Results

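Gene expression was measured by RNA sequencing in HSPCs from the bone marrow of aged wild-type mice. HSPCs are the cells from which the blood lineages are renewed. One group of 3 libraries came from cells given vehicle and the other group of 3 from cells given uridine, a nucleoside that cells take up and phosphorylate to make pyrimidine nucleotides. The labels give neither dose nor duration, nor the markers by which the cells were sorted. The vehicle libraries held 17449008, 17890834 and 18037717 counts and the uridine libraries 17083635, 18638627 and 16109265. The study's title concerns uridine in the ageing of the blood system, and the single comparison the design allows asks which transcripts differ between aged HSPCs with and without it.

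In uridine-treated cells 18 of 24 monocyte, macrophage and dendritic cell markers and 18 of 23 neutrophil genes fell, with adjusted p of 4.4e-18 and 5.2e-15 in the test of each list. Among the nuclear genes of the respiratory chain 32 of 72 rose (adjusted p = 6.1e-09), and 23 with a correction for gene length. With a correlation estimated per list, camera's adjusted p was 0.016 for each of these lists. Of 14706 genes tested, 2544 (17.3%) changed, 1056 of them rising and 1488 falling. Most changes were small, with a median of 1.15-fold among the genes that rose and 1.18-fold among those that fell. Larger changes were mostly falls: 195 genes fell and 43 rose by 2-fold or more. The values of the groups did not overlap for 4533 genes (30.8%), where chance gives 10%, and 2420 of the changed genes were among them. The first principal component held 41.3% of the variance and separated the groups. Among the changed genes, 194 are predicted genes or pseudogenes. With DESeq2's Wald test the number of rising genes was 688, and in the test against a 1.5-fold change 143 genes were called, 141 falling and 2 rising. One of these 2 was Prss34 and the other a predicted gene.

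Among protein-coding genes with a mean log2 CPM of at least 1 and no overlap between the groups, the 8 largest falls were those of Saa3, Acod1, Cp, Cntnap1, Cxcl10, Cx3cr1, Entpd4b and Hp. Saa3 (ENSMUSG00000040026; chromosome 7, 46711998 to 46715700 in mm10) encodes an inducible serum amyloid A and fell by 4.49 on the log2 scale (SE 0.26), from 10.1 ± 1.02 to 0.456 ± 0.268 CPM (SD, n = 3, adjusted p = 2.7e-24). Acod1 (ENSMUSG00000022126; chromosome 14, 103046977 to 103056573), whose enzyme makes itaconate in activated macrophages, changed by -4.45 ± 0.29, from 7.73 ± 0.635 to 0.34 ± 0.263 CPM. Cp, the copper-carrying ferroxidase ceruloplasmin, changed by -3.30 ± 0.26, and Hp, the haemoglobin-binding haptoglobin (ENSMUSG00000031722; chromosome 8, 109575128 to 109579172), by -2.62 ± 0.068, from 83.7 ± 4.64 to 13.6 ± 0.629 CPM. The others were the interferon-inducible chemokine gene Cxcl10 (-2.91 ± 0.34), the fractalkine receptor gene Cx3cr1 (-2.68 ± 0.12), the axonal adhesion gene Cntnap1 (-2.91 ± 0.19) and Entpd4b (-2.66 ± 0.24). Entpd4b is uncertain because a near-identical copy, Entpd4, may share its reads. The smallest p-values among falling genes belonged to Mpo (ENSMUSG00000009350; chromosome 11, 87793581 to 87804413), the myeloperoxidase of neutrophil granules, which fell from 1945 ± 33.1 to 1044 ± 27.8 CPM (-0.90 ± 0.016, adjusted p = 1.3e-50), to Hp, to Cybb, the catalytic subunit of the phagocyte NADPH oxidase (-2.55 ± 0.072, from 71.7 ± 0.39 to 12.2 ± 1.22 CPM), and to the granule protease gene Prtn3 (-0.85 ± 0.026).

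Within the same limits rises were smaller. The largest was that of Prss34 (ENSMUSG00000056399; chromosome 17, 25298394 to 25300161), a mast cell and basophil protease gene, by 1.30 ± 0.13, from 5.61 ± 0.189 to 13.8 ± 1.19 CPM (adjusted p = 1.3e-12). The mast cell chymase gene Cma1 rose by 0.91 ± 0.17, from 4.1 ± 0.412 to 7.73 ± 0.798 CPM. Ltf, which encodes the neutrophil granule protein lactoferrin, rose by 1.13 ± 0.19 at a low level, from 2.94 ± 0.49 to 6.45 ± 0.978 CPM. Phactr1, a regulator of actin and protein phosphatase, rose by 1.03 ± 0.30, the B-cell coactivator gene Pou2af1 by 0.96 ± 0.26 and the stress-induced transcription factor gene Atf3 by 0.93 ± 0.24. The call of Phactr1 was lost without uridine replicate 1 (0.058), with the adjusted p in brackets here and in like cases. Efcab5 (0.82 ± 0.28) and Mypop (0.81 ± 0.28) were present at under 3 CPM in either group. The call of Efcab5 was lost without vehicle replicate 1 or 3 (0.112 and 0.094) or uridine replicate 1 or 3 (0.102 and 0.123) and with DESeq2's Wald test (0.071). That of Mypop was lost without vehicle replicate 1 or 3 (0.117 and 0.111) or uridine replicate 1 or 3 (0.224 and 0.076), with DESeq2's Wald test (0.089), with limma-voom (0.066) and with no count filter (0.054). The smallest p-values among rising genes belonged to mt-Cytb, the mitochondrially encoded cytochrome b (0.26 ± 0.013, from 2431 ± 22.1 to 2912 ± 28.2 CPM), to Pf4, which encodes platelet factor 4 (0.28 ± 0.019, from 741 ± 19.7 to 901 ± 14.7 CPM), to Egr1, an immediate-early transcription factor gene (0.44 ± 0.033, from 131 ± 2.1 to 178 ± 3.15 CPM), and to the urea transporter gene Slc14a1 (0.35 ± 0.027).

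**Figure D1:**
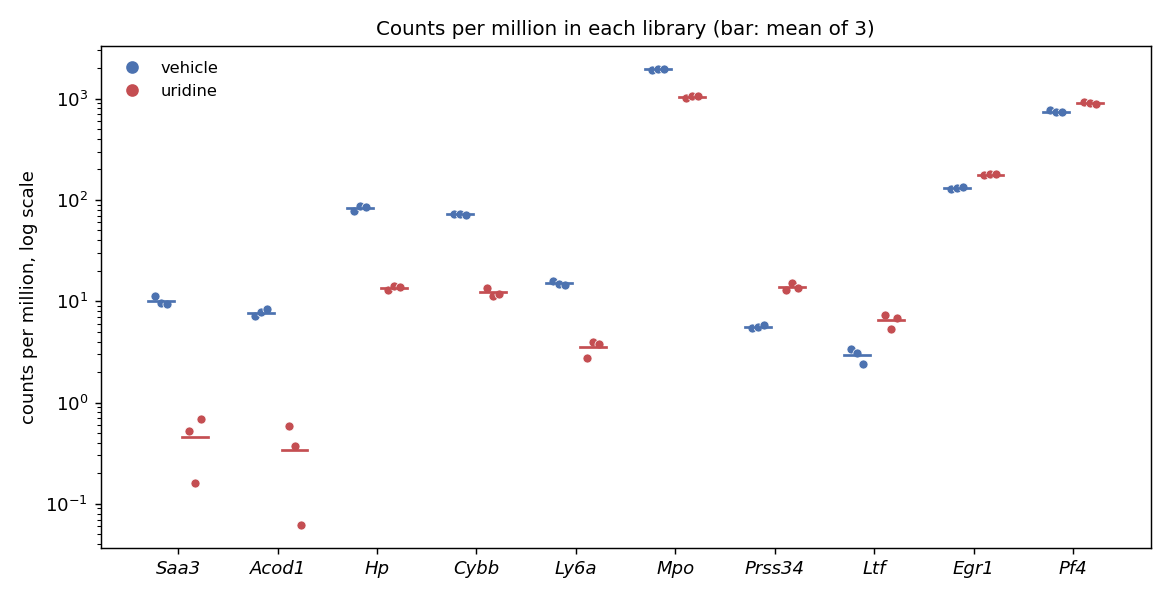
CPM of 10 named genes, on a log axis, in each of the 3 vehicle (blue) and 3 uridine (red) libraries, with a bar at each group's mean. The groups do not overlap for any gene shown, which was a condition for choosing Saa3, Acod1, Hp, Prss34 and Ltf. The falls of Saa3, from 10.1 to 0.456 CPM, and Acod1, from 7.73 to 0.34 CPM, are larger as folds than the rise of Prss34 from 5.61 to 13.8 CPM.

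Of the 40 gene lists, 14 differed from the other genes at an adjusted p under 0.05, 7 upward and 7 downward. With a correlation estimated per list 6 of the 14 stayed past 0.05: the monocyte, neutrophil, interferon, NF-kB and ER stress lists downward and the nuclear respiratory chain list upward. Both lists of mature myeloid markers were lower with uridine. Of 24 measured monocyte, macrophage and dendritic cell markers, 18 fell and 0 rose (18 and 1 adjusted over the list alone), with a median of -0.85 and an adjusted p of 4.4e-18 in camera (0.016 with an estimated correlation). They included the monocyte surface marker gene Ly6c2 (-1.35 ± 0.049), which has a near-identical neighbour in Ly6c1, the lysozyme gene Lyz2 (-0.87 ± 0.033, from 209 ± 4.96 to 115 ± 0.854 CPM), the chemokine receptor gene Ccr2 (-2.03 ± 0.08) and Csf1r, the receptor for macrophage colony-stimulating factor (-1.65 ± 0.065). Of 23 neutrophil and granule genes, 18 fell and 1 rose, with the same counts adjusted over the list alone, a median of -0.77 and an adjusted p of 5.2e-15 (0.016 with an estimated correlation). The granule protease genes Elane (-0.99 ± 0.032, from 229.6 ± 5.3 to 115 ± 2.39 CPM) and Prtn3 fell with Mpo and Hp. The gene that rose was Ltf.

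**Figure D2:**
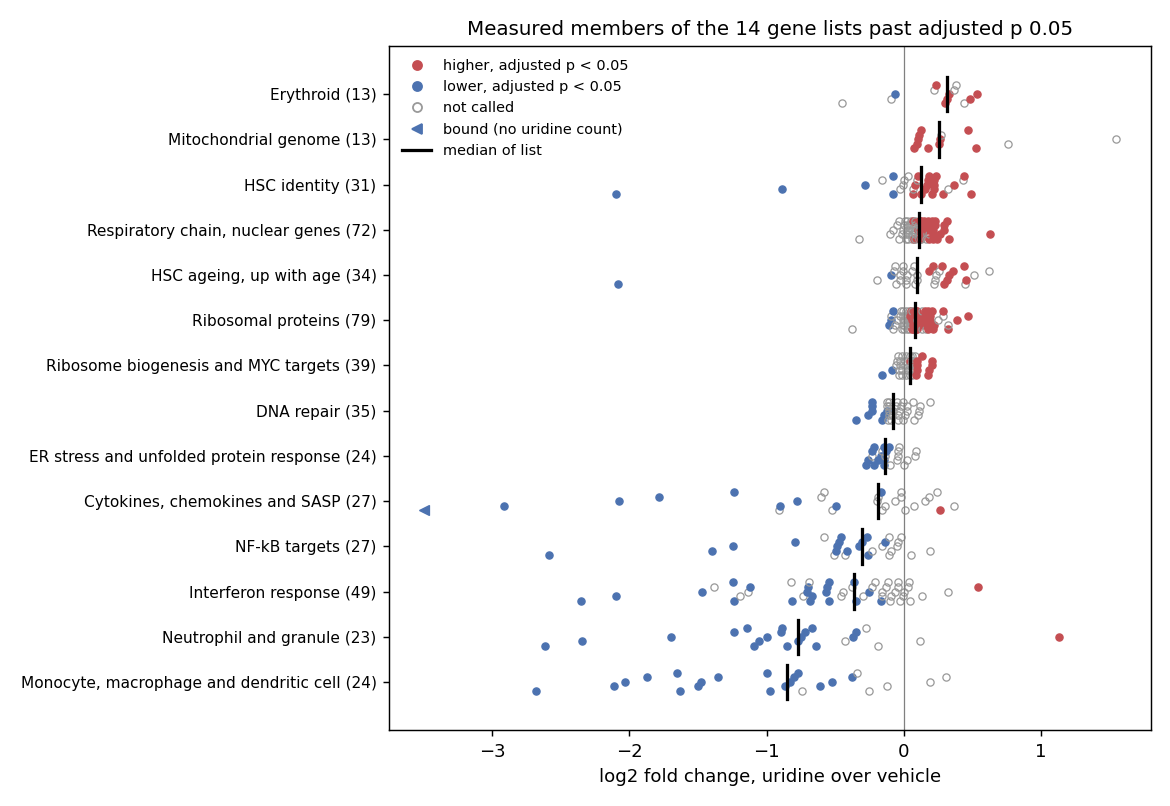
Log2 fold change (uridine over vehicle) of the measured members of the 14 gene lists past adjusted p 0.05, with the number measured in brackets, 1 symbol per gene. Filled symbols are genes with adjusted p under 0.05, open symbols other members, black lines list medians, and the triangle is Mmp13, which had no count in the uridine libraries and is drawn at the bound that 3 counts over that group give. The medians run from -0.85 for the monocyte list to 0.31 for the erythroid list, the latter with an adjusted p of 0.171 under an estimated correlation.

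Lists of inflammatory signalling were lower too. Of 49 interferon-stimulated genes, 19 fell and 1 rose (24 and 1 adjusted over the list alone), with a median of -0.36 (adjusted p = 5.6e-09; 0.016 with an estimated correlation). Gbp3 (-0.70 ± 0.10), Parp14 (-0.35 ± 0.052) and Oas3 (-0.71 ± 0.12), all induced by interferon, were among those that fell. The member that rose was the interferon-inducible GTPase gene Tgtp2 (0.54 ± 0.15), named after its values were seen. Its call was lost without vehicle replicate 3 (0.0502) or uridine replicate 1 (0.088). Members of the Gbp, Ifi and Tgtp families have close copies that may share reads. Of 27 NF-kB targets, 14 fell and 0 rose (16 and 1 adjusted over the list alone), with a median of -0.30 (adjusted p = 1.2e-08; 0.02 with an estimated correlation). They included Tnip1 (-0.48 ± 0.047), Tnip3 (-1.40 ± 0.15) and Tnfaip3 (-0.47 ± 0.078), which restrain NF-kB signalling, and the NF-kB cofactor gene Bcl3 (-1.25 ± 0.15). Among 27 cytokine, chemokine and senescence-associated secretory genes, 9 fell and 1 rose, with the same counts adjusted over the list alone. This list's adjusted p was 2.1e-04 but 0.059 with an estimated correlation and 0.187 when genes under a mean of 50 counts were left out. The chemokine gene Ccl9 (-0.77 ± 0.045), the macrophage elastase gene Mmp12 (-2.07 ± 0.21) and Igfbp4 (-0.17 ± 0.024) fell with Cxcl10. The member that rose was the growth factor gene Vegfa (0.26 ± 0.095), named after its values were seen. Its call was lost without vehicle replicate 1 or 3 (0.113 and 0.233) or uridine replicate 2 (0.358, the log2 value being 0.16), with DESeq2's Wald test (0.136), with limma-voom (0.06) and with no count filter (0.059). In the same libraries the monocyte markers had the median of -0.85 given above and the neutrophil genes that of -0.77. ER chaperone and unfolded protein response genes fell by small amounts. Of 24 measured, 12 fell and 0 rose, also adjusted over the list alone, with a median of -0.14 (adjusted p = 3.0e-05; 0.049 with an estimated correlation), among them the chaperone genes Hyou1 (-0.27 ± 0.025), Calr (-0.16 ± 0.016) and Hspa5 (-0.13 ± 0.017) and Edem1 (-0.22 ± 0.028), which acts in the degradation of misfolded proteins.

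Of 31 HSC identity genes, 17 rose and 5 fell (19 and 5 adjusted over the list alone), with a median of 0.13 (adjusted p = 0.0015, but 0.077 with an estimated correlation). In the same libraries the monocyte list had a median of -0.85 and the neutrophil list one of -0.77. Egr1 rose as given above, and Gata2, a transcription factor gene of stem cells and of mast cell and megakaryocyte progenitors, rose by 0.22 ± 0.026, from 266 ± 2.26 to 309 ± 9.88 CPM. Ly6a (ENSMUSG00000075602; chromosome 15, 74994877 to 74998031), which encodes the stem cell marker Sca-1 and is also induced by interferon, fell by 2.10 on the log2 scale (SE 0.15), from 15.0 ± 0.838 to 3.5 ± 0.659 CPM. The labels do not say whether Sca-1 was used to sort the cells. Gfi1, a repressor needed in both stem cells and neutrophil differentiation, changed by -0.89 ± 0.10. The other members that fell, named after their values were seen, were Ifitm1 (-0.28 ± 0.035), Etv6 (-0.075 ± 0.022) and Runx1 (-0.079 ± 0.028). The call of Etv6 was lost without vehicle replicate 2 (0.118), with the length trend removed (0.088) and with the length and GC trends removed (0.063). That of Runx1 was lost without vehicle replicate 1 or 3 (0.095 and 0.133) or uridine replicate 1 or 3 (0.247 and 0.051), with DESeq2's Wald test (0.093), with no count filter (0.066), with the length trend removed (-0.013 with adjusted p 0.831), with the length and GC trends removed (-0.012 with adjusted p 0.833) and with scaling by library size alone (0.071). Kit, the stem cell factor receptor gene, rose by 0.07 ± 0.023, from 365 ± 1.64 to 383 ± 3.12 CPM (adjusted p = 0.024). That call was lost without vehicle replicate 2 (0.076) or uridine replicate 2 or 3 (0.086 and 0.064) and with no count filter (0.08), while the value was 0.11 with the length trend removed (adjusted p = 8.0e-05). The stem cell marker gene Procr (-0.16 ± 0.19, adjusted p = 0.646) and the progenitor marker gene Cd34 (-0.0052 ± 0.02, adjusted p = 0.906) were not called. Procr was at -0.067 without vehicle replicate 1, and the sign of Cd34 changed under several alternatives. Of 34 genes described as higher in aged than in young HSCs, 9 rose and 2 fell, with the same counts adjusted over the list alone (median 0.10, adjusted p = 0.0073, but 0.11 with an estimated correlation). Without vehicle replicate 2 the median was 0.15. Egr1, Aldh1a1 (0.36 ± 0.045), Ehd3 (0.29 ± 0.038) and Clu (0.28 ± 0.044) rose. Those that fell, named after their values were seen, were the oxysterol receptor gene Gpr183 (-2.08 ± 0.42) and the von Willebrand factor gene Vwf (-0.091 ± 0.02). The call of Vwf was lost with the length trend removed (-0.0047 with adjusted p 0.92) and with the length and GC trends removed (-0.0081 with adjusted p 0.85).

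Of 27 erythroid genes listed, 13 passed the count filter. Among these 13, 6 rose and 1 fell (8 and 2 adjusted over the list alone). Their median was 0.31 (list adjusted p = 0.0035, but 0.171 with an estimated correlation). The monocyte and neutrophil lists had medians of -0.85 and -0.77 in the same libraries. The carbonic anhydrase gene Car2 rose by 0.30 ± 0.025, the water channel gene Aqp1 by 0.53 ± 0.10, the nuclear factor gene Hemgn by 0.33 ± 0.056 and Epor, the erythropoietin receptor gene, by 0.49 ± 0.11. The member that fell was the transferrin receptor gene Tfrc (-0.066 ± 0.024), named after its values were seen. Its call was lost without vehicle replicate 1 or 3 (0.051 and 0.283) or uridine replicate 1, 2 or 3 (0.072, 0.067 and 0.147), with DESeq2's Wald test (0.09), with no count filter (0.094), with the length trend removed (-0.043 with adjusted p 0.236), with the length and GC trends removed (-0.017 with adjusted p 0.707) and with scaling by library size alone (0.09). Among 23 megakaryocyte and platelet genes, 10 rose and 4 fell (12 and 5 adjusted over the list alone), and the list was not past the threshold (adjusted p = 0.071). Pf4, Slc14a1 and the integrin gene Itga2b (0.16 ± 0.017) rose while the thrombospondin gene Thbs1 changed by -0.38 ± 0.029. Mast cell, basophil and eosinophil genes went both ways, 5 of 23 rising and 5 falling (6 and 5 adjusted over the list alone; list adjusted p = 0.996). Prss34 and the monoamine transporter gene Slc18a2 (0.23 ± 0.041) rose, and the cytokine receptor genes Il6st (-0.73 ± 0.041) and Csf2rb2 (-0.45 ± 0.059) fell. Csf2rb2 has a near-identical copy in Csf2rb. Of 21 lymphoid genes 1 rose and 6 fell (2 and 6 adjusted over the list alone; list adjusted p = 0.684), the falls including Notch1 (-0.53 ± 0.054), the receptor gene Flt3 (-0.32 ± 0.041), Dntt (-0.84 ± 0.11), which encodes the template-free polymerase of lymphoid progenitors, and Ikzf1 (-0.18 ± 0.027). Stromal and endothelial markers were mostly below the count filter, and of 8 measured 1 rose and 2 fell, also adjusted over the list alone (list adjusted p = 0.338).

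Of 72 nuclear genes of the respiratory chain and ATP synthase, 32 rose and 0 fell (33 and 0 adjusted over the list alone), with a median of 0.11 (adjusted p = 6.1e-09; 0.016 with an estimated correlation). Examples are the cytochrome oxidase gene Cox7c (0.33 ± 0.041) and the ATP synthase genes Atp5k (0.63 ± 0.083), Atp5g2 (0.23 ± 0.033) and Atp5e (0.26 ± 0.038). With the length trend removed 23 genes of this list rose and 0 fell, with a median of 0.082. Of 13 protein genes of the mitochondrial genome, 10 rose and 0 fell (13 and 0 adjusted over the list alone), with a median of 0.26 (adjusted p = 5.4e-07, but 0.171 with an estimated correlation). Without uridine replicate 1 this median was 0.17, and 6 genes rose with the length trend removed. Besides mt-Cytb they included mt-Nd4 (0.18 ± 0.017), mt-Nd1 (0.13 ± 0.014) and mt-Co2 (0.47 ± 0.055). With the length trend removed mt-Nd1 stood at 0.057. Mitochondrially encoded transcripts took 1.81% ± 0.0095 of counts in vehicle and 1.98% ± 0.026 in uridine libraries (SD, n = 3; exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give). Of 79 cytosolic ribosomal protein genes, 42 rose and 3 fell (46 and 4 adjusted over the list alone), with a median of 0.079 (adjusted p = 5.1e-08, but 0.208 with an estimated correlation), and with a median of 0.051, 33 rising and 7 falling when the length trend was removed. Rplp0 (0.18 ± 0.014), Rpl11 (0.21 ± 0.019), Rps28 (0.32 ± 0.03) and Rps18 (0.18 ± 0.017) rose, and Rpl4 (-0.11 ± 0.014), Rpl6 (-0.093 ± 0.018) and Rpl23a (-0.08 ± 0.024), named after their values were seen, fell. The call of Rpl23a was lost without vehicle replicate 1 or 2 (0.132 and 0.064) or uridine replicate 2 (0.082), while its value was -0.16 with the length trend removed. Of 39 genes of ribosome biogenesis and MYC targets, 10 rose and 2 fell, with the same counts adjusted over the list alone. This list was at the threshold (adjusted p = 0.047, but 0.234 with an estimated correlation), and was past it in 1 of the 6 fits that left out a library, the one without vehicle replicate 2, with adjusted p from 0.042 to 0.145 over the 6. Mycn (0.20 ± 0.034), Gnl3 (0.13 ± 0.03) and Nob1 (0.18 ± 0.043) rose, while Utp20 (-0.16 ± 0.031, but -0.10 with the length trend removed) and, named after its values were seen, Myc (-0.083 ± 0.028) fell. The call of Myc was lost without vehicle replicate 1 or 3 (0.162 and 0.066) or uridine replicate 1 or 2 (0.159 and 0.246), with DESeq2's Wald test (0.107) and with scaling by library size alone (0.062). Fold changes also ran with gene length in these libraries: the median was 0.11 in the shortest decile of tested genes (48 to 1070 bases) and -0.059 in the longest (9299 to 123179 bases). The median length was 3875 bases over all tested genes, 1739 bases for the ribosomal protein list, 1710 bases for the nuclear respiratory chain list and 784 bases for the mitochondrial genome list.

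**Figure D3:**
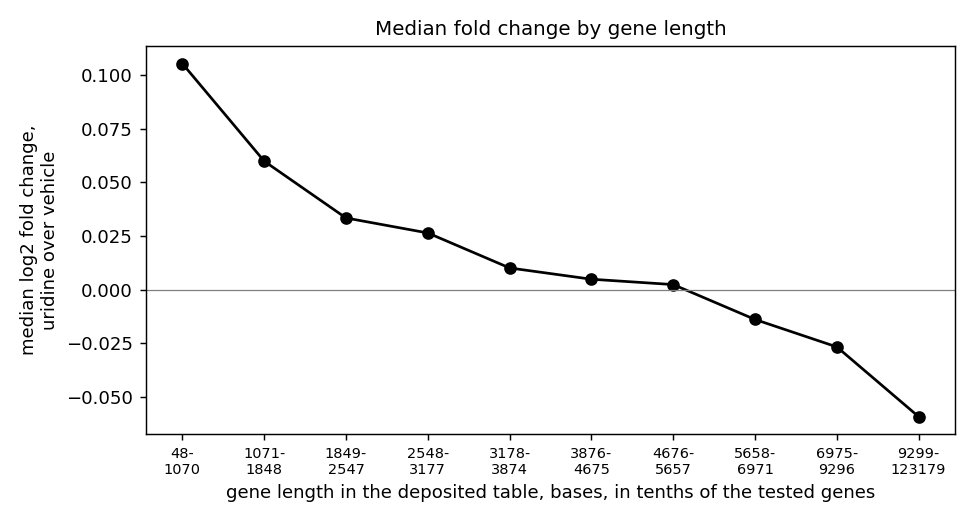
Median log2 fold change (uridine over vehicle) of the tested genes in deciles by the gene length given in the deposited table, with the range of lengths in bases under each point. The medians fall from 0.11 in the shortest decile to -0.059 in the longest.

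Of the genes nearest to uridine uptake and use, the uridine kinase genes were not called, and nucleoside transporter genes fell or were not called. Of the nucleoside transporter genes, Slc28a2, which imports nucleosides with sodium, changed by -0.37 ± 0.058, from 57.3 ± 0.854 to 44.4 ± 2.12 CPM (adjusted p = 5.6e-07). The equilibrative transporter genes Slc29a3 (-0.22 ± 0.062, adjusted p = 0.0053) and Slc29a1 (-0.16 ± 0.053, adjusted p = 0.024) fell slightly, and Slc29a2 was not called (0.0027 ± 0.13, adjusted p = 0.993). The call of Slc29a3 was lost without vehicle replicate 2 (0.055). That of Slc29a1 was lost without vehicle replicate 1 or 2 (0.099 and 0.144) or uridine replicate 1 or 3 (0.075 and 0.067) and with DESeq2's Wald test (0.069). The uridine kinase genes Uck1 (0.12 ± 0.059, adjusted p = 0.174) and Uck2 (-0.015 ± 0.024, adjusted p = 0.762) and the cytidine deaminase gene Cda (0.14 ± 0.30, adjusted p = 0.827) were not called. The signs of Slc29a2, Uck2 and Cda changed under some alternatives. Upp1, the uridine phosphorylase gene, stood at 3.67 ± 1.38 CPM in vehicle and 5.30 ± 1.03 CPM in uridine libraries (0.53 ± 0.21) and missed the threshold (adjusted p = 0.067), passing it at 0.82 without vehicle replicate 3 (adjusted p = 0.0089) and at 0.64 without uridine replicate 3 (adjusted p = 0.032). Without vehicle replicate 1 it stood at 0.28 (adjusted p = 0.437). None of 4 lists nearest to nucleotides was past the threshold in camera: 38 genes of pyrimidine nucleotide metabolism (4 rising and 4 falling; 6 and 4 adjusted over the list alone; list adjusted p = 0.176), 14 of uridine transport and receptors (1 rising and 3 falling; 2 and 3 adjusted over the list alone; 0.920), 26 of UDP-sugar and hexosamine synthesis (3 and 3; 4 and 4 adjusted over the list alone; 0.941) and 24 of purine metabolism (3 rising and 4 falling; 3 and 5 adjusted over the list alone; 0.338). With fry, which does not compare a list with other genes, the pyrimidine list passed upward (adjusted p = 0.026) and the purine list downward (adjusted p = 0.0014). The ribonucleotide reductase gene Rrm2 (-0.19 ± 0.029) fell, as did the purine-degrading genes Gda (-1.16 ± 0.073) and Xdh (-1.24 ± 0.13). Medians of the monocyte and neutrophil lists were -0.85 and -0.77 in the same libraries, and a link to these falls was not tested.

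Cell cycle genes changed little as groups. Of 35 DNA repair genes, 8 fell and 0 rose (11 and 2 adjusted over the list alone), with a median of -0.076 (list adjusted p = 0.0073, but 0.111 with an estimated correlation). The call was lost when the trend with gene length was removed (median -0.049, adjusted p = 0.0506) and when those with length and GC content were (median -0.048, adjusted p = 0.083). Prkdc (-0.35 ± 0.045), Brca2 (-0.23 ± 0.045, but -0.15 with the length and GC trends removed) and Fancd2 (-0.26 ± 0.056) fell, and so did H2afx (-0.16 ± 0.027), the histone gene whose product marks DNA breaks. In the G2/M list 9 of 40 genes fell and 0 rose, also adjusted over the list alone (list adjusted p = 0.262), with the proliferation marker gene Mki67 at -0.17 ± 0.018, from 1002 ± 25.7 to 891 ± 15.3 CPM. With the length and GC trends removed Mki67 stood at -0.11. Of 40 DNA replication genes 4 fell and 0 rose, also adjusted over the list alone (list adjusted p = 0.182). Of 27 genes of cell cycle inhibitors and quiescence 7 rose and 4 fell, also adjusted over the list alone (list adjusted p = 0.694). They included the cell cycle kinase gene Cdk6 (-0.34 ± 0.018, from 936 ± 6.43 to 741 ± 3.07 CPM), the thioredoxin inhibitor gene Txnip (0.27 ± 0.025, from 287 ± 4.06 to 346 ± 7.32 CPM) and Klf4 (-1.63 ± 0.22). Klf4 also belongs to the monocyte list, whose median was -0.85. The cell cycle inhibitor genes Cdkn1a (-0.078 ± 0.036, adjusted p = 0.135) and Cdkn2a (0.27 ± 0.14, adjusted p = 0.184) were not called, though Cdkn1a was at -0.11 without vehicle replicate 2 (adjusted p = 0.047) and Cdkn2a at 0.16 without uridine replicate 2. Of 29 p53 targets 1 rose and 7 fell (1 and 8 adjusted over the list alone; list adjusted p = 0.343), with the pro-apoptotic gene Pmaip1 at -1.68 ± 0.11, from 21.8 ± 0.989 to 6.82 ± 0.0684 CPM.

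The remaining lists were not past the threshold. Of 22 adhesion and homing genes 4 rose and 9 fell, also adjusted over the list alone (list adjusted p = 0.125), including the phagocytosis-inhibiting receptor gene Cd47 (-0.23 ± 0.02, from 639 ± 13.8 to 546 ± 3.85 CPM). In the list of MAPK feedback and immediate-early genes 5 of 39 rose and 2 fell (6 and 2 adjusted over the list alone; list adjusted p = 0.144), with rises of Egr1, Atf3 and Fosb (0.41 ± 0.09) and a fall of Fosl2 (-0.55 ± 0.094). Of 37 lysosome and autophagy genes 4 rose and 10 fell (6 and 10 adjusted over the list alone; list adjusted p = 0.338), with the protease gene Ctsz at -0.56 ± 0.039 and the tetraspanin gene Cd63 at 0.27 ± 0.027. The 27 glycolysis genes included 4 that rose and 5 that fell (6 and 5 adjusted over the list alone; list adjusted p = 0.814), with the myeloid hexokinase gene Hk3 at -0.56 ± 0.035, Pgam1 at -0.31 ± 0.025 and the lactate dehydrogenase gene Ldha at 0.12 ± 0.018. For 10 nuclear-retained RNAs 1 rose and 3 fell, also adjusted over the list alone (list adjusted p = 0.684), with Malat1 at -0.31 ± 0.02 and Xist at -0.11 ± 0.013. The call of Xist was lost with the length trend removed (-0.019 with adjusted p 0.389) and with the length and GC trends removed (-0.0027 with adjusted p 0.931). Rising and falling genes numbered 3 and 1 of 11 for cholesterol efflux (the same adjusted over the list alone; list adjusted p = 0.338), 2 and 4 of 32 for cholesterol and fatty acid synthesis (the same adjusted over the list alone; 0.941) and 2 and 3 of 27 for the TCA cycle (the same adjusted over the list alone; 0.941). They numbered 5 and 3 of 37 for the integrated stress response (7 and 4 adjusted over the list alone; 0.506), 3 and 3 of 19 for heat shock (the same adjusted over the list alone; 0.941) and 6 and 7 of 30 for antioxidant genes (7 and 7 adjusted over the list alone; 0.941). For hypoxia they were 2 and 5 of 24 (2 and 6 adjusted over the list alone; 0.771), for apoptosis 2 and 4 of 25 (2 and 5 adjusted over the list alone; 0.737) and for replication-dependent histones, whose transcripts mostly escape poly-T capture, 1 and 0 of 13 (the same adjusted over the list alone; 0.743). The median, the mean and the test differed in sign in the lists of integrated stress response, lymphoid, nuclear-retained RNA, cell cycle inhibitor, hypoxia, glycolysis, antioxidant, heat shock, TCA cycle and mast cell genes.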

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

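Scaling by library size alone, the correction for gene length without the block and that for length and GC content were added after the data had been seen. The number of changed genes was 2544 and ran from 1861 with DESeq2's Wald test to 2594 with scaling by library size alone, apart from the test against a 1.5-fold change, which called 143 genes, 2 rising and 141 falling, because it asks for larger changes. Rising genes numbered 688 with DESeq2's Wald test against 1056; the cause was not tested. Without 1 library the counts ran from 2060 to 2229 changed, 799 to 867 rising and 1234 to 1367 falling. Of the 14 lists past the threshold, 6 stayed past it with an estimated correlation, which takes each list's own value in place of 0.01. Among the lists lost, the estimate was below 0.01 for HSC identity (-0.013), HSC ageing (-0.014), cytokine (-0.0024) and DNA repair (0.003) genes. A larger correlation is therefore not why those calls were lost. For the neutrophil list too the estimate was below 0.01 (-0.021), yet its adjusted p went from 5.2e-15 to 0.016. The setting thus changes more in the test than the correlation. A call lost under it does not by itself show that a list's genes vary together. The estimate was above 0.01 for the ribosomal protein (0.11), mitochondrial (0.27), erythroid (0.049) and ribosome biogenesis (0.013) lists. With fry 24 lists passed, including all 14; it tests whether a list's genes move on balance and not whether they differ from other genes. The 10 added were megakaryocyte, pyrimidine and immediate-early genes upward and stromal, purine, glycolysis, G2/M, p53, lysosome and adhesion genes downward. The other settings gave 12 to 14 lists. When genes under a mean of 50 counts were left out, 2 of the 14 lists lost their call, the cytokine list among them.

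No clear pairing by replicate number was seen. The deviations of same-numbered libraries from their group means correlated at 0.013, 0.029 and 0.012, and those of differently numbered ones at -0.038 to 0.024. Vehicle 3 and uridine 1 correlated best with each other, and the remaining libraries with their own number. Correlations this small do not exclude a weak pairing. With a replicate block 2400 genes changed, 972 rising and 1428 falling, and 13 lists passed, without that of ribosome biogenesis (adjusted p = 0.088). Among named genes Mypop (0.057) and Tfrc (0.058) left the threshold and no other call changed. With the block and a gene length correction 2096 changed, 948 rising and 1148 falling.

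Over the 137 genes named in the text and their alternatives, 2255 values kept their direction and their side of the threshold, 173 lost a call (93 of them in the 1.5-fold test), 3 gained one and 17 changed sign. With at least 50 counts on average, and among protein-coding genes without mitochondrial ones, 128 of the 137 genes were tested, and the others have no value there. The 17 belong to 4 genes that were not called. Uck2 stood at 0.0014 with the gene length correction, with or without the block. Slc29a2 stood at -0.016 with the block and length correction, -0.018 with the length correction and -0.025 with length and GC, and from -0.098 to 0.13 without 1 library. Cd34 stood at 0.027 with the block and length correction and with the length correction, 0.029 with length and GC, 0.0039 with scaling by library size alone, and from -0.017 to 0.015 without 1 library. Cda ran from -0.083 to 0.42 without 1 library. The cause was not tested. At 16109265 to 18638627 counts per library, changes of 1.1-fold were mostly missed in simulated data. Of such genes, all with a mean above 50 counts, 18% were recovered, so small changes among uncalled genes are not excluded.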

Other observations

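The gene groups in this paragraph, the immunoglobulin genes and plasma cell markers, both tests of a loss of cells and the comparison of each corrected median with its own fit were chosen after the results were seen, as were the settings with library-size scaling and with the length and GC corrections. No test of enrichment was made on these groups, and monocyte and neutrophil markers fell in the same libraries (medians -0.85 and -0.77). Of 9 measured acute-phase and complement genes, 2 of them also in those lists, 7 fell and 0 rose, with a median of -1.95, including the complement component gene C3 (-2.07 ± 0.065, from 73.2 ± 0.746 to 17.4 ± 0.0812 CPM) and the protease inhibitor gene Slpi (-1.95 ± 0.12) besides Saa3, Cp and Hp. Of 6 measured genes of the phagocyte NADPH oxidase, which makes superoxide, 4 fell and 0 rose, Cybb most, with Ncf1 at -0.72 ± 0.039. Of 16 Toll-like receptors and their partners 8 fell and 0 rose (median -0.76), among them Tlr2 (-0.77 ± 0.10) and the trafficking chaperone gene Unc93b1 (-0.75 ± 0.043, from 114 ± 3.54 to 67.7 ± 0.925 CPM). Of 5 Fc receptor genes 3 fell and 0 rose, including Fcgr2b (-1.11 ± 0.072) and Fcgr3 (-0.82 ± 0.11). Of 6 measured mast cell and basophil protease genes 4 rose and 1 fell, while the fixed list of mast cell, basophil and eosinophil genes went both ways (5 rising and 5 falling of 23, adjusted p = 0.996). Tpsb2 rose by 1.27 ± 0.38 and Mcpt4 by 1.16 ± 0.37, both at under 2 CPM, with Prss34 and Cma1. The call of Tpsb2 was lost without uridine replicate 1 (0.058) and that of Mcpt4 was lost without vehicle replicate 2 or 3 (0.066 and 0.119) or uridine replicate 1 or 3 (0.075 and 0.132) and with DESeq2's Wald test (0.05004). The basophil protease gene Mcpt8 changed by -0.36 ± 0.069, from 39.3 ± 1.08 to 30.7 ± 1.51 CPM. Mmp13, a collagenase gene at 0.655 CPM with vehicle before normalization, had no count in the uridine libraries and was at least 11.3-fold lower, taking 3 counts over the group as the floor.

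Monocyte and neutrophil genes were lower with uridine in both fixed lists. The TMM factors ran from 0.996 to 1.004, too close to 1 to make falls of this size. Scaling by library size alone could therefore hardly move the medians, and left them at -0.84 for the monocyte and -0.76 for the neutrophil list. Removing the trends with gene length and GC content left them at -0.87 and -0.84. The tables thus argue against the TMM factors and those trends as the cause. The loss of a single cell type that alone carries these transcripts would lower all of them by 1 common fold. The members' log2 fold changes had an SD of 0.76 against a median SE of 0.12, so they did not fall by 1 fold. This does not decide the question, since the lists mark several cell types and the spread was known when the explanation was framed. A candidate explanation is a smaller share of cells on the granulocyte and monocyte path whose transcripts other progenitors also carry. The share of members that fell, 76.6% of the 47 measured, does not decide it, since the falls were known when the explanation was framed. Lower transcription of these genes within the same cells would give the same values, and these tables do not separate the 2. An effect of uridine on either stays open as untested. A changed share of cells would also move the HSC identity and erythroid lists, which was not tested. The sort that defined the cells is not in the labels, 24 of 31 and 23 of 26 list members pass the count filter in these HSPCs, and 2 members of each list also belong to another list.

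Ribosomal protein, nuclear respiratory chain and mitochondrially encoded genes rose in libraries where short genes in general were higher. With an estimated correlation, however, the calls of the ribosomal protein list (adjusted p = 0.208) and of the mitochondrial list (0.171) were lost, and the list tests below use the fixed correlation. With the length trend of all other genes removed, the median of the ribosomal proteins went from 0.079 to 0.052 (adjusted p = 0.0017 in the list test), that of the respiratory chain from 0.11 to 0.083 (adjusted p = 1.8e-04) and that of the mitochondrially encoded genes from 0.26 to 0.18 (adjusted p = 4.2e-04). Without 1 library, the corrected median kept 60.5 to 75.7%, 65.3 to 72.8% and 55.3 to 78.9% of the uncorrected median of the same libraries. The fitted length trend thus left part of each median, but the fit may remove too little. Tested genes of 1071 to 1848 bases, the lists' own members included, had a median of 0.060 before correction. For the ribosomal protein list (0.079) the length trend therefore stays open as the whole cause. The respiratory chain list (0.11) lay further above that value, but close to the 0.11 of genes of 48 to 1070 bases. Its members differ in length, Atp5k having 616 bases, so the length trend stays open there too. The mitochondrial list (0.26) lay above the 0.11 of genes of 48 to 1070 bases. That decile pools lengths, and the estimated correlation of the mitochondrial genes was 0.27, so this excess does not exclude the trend. For both lists the length trend may account for part or all of the rise. The length trend itself follows the groups (exact two-sided permutation p = 0.1 for the slope of each library, the smallest 3 against 3 can give), and whether it comes from RNA handling or from the cells was not tested.

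Some immunoglobulin transcripts were lower with uridine, without a test of enrichment on them. Of 10 constant-region and joining-chain genes 6 fell and 0 rose, among them Igha (-0.74 ± 0.032, from 212 ± 3.86 to 127 ± 4.07 CPM), Igkc (-0.66 ± 0.051), Ighm (-0.45 ± 0.041) and Jchain (-0.71 ± 0.065), and of 37 variable and joining segments 8 fell and 1 rose; segments share sequence and their counts are uncertain. Fewer plasma cells, or less RNA from them in the culture, may be the source, and a sort for HSPCs would remove such cells. The 12 measured plasma cell markers had a median of -0.026, with 1 rising (Pou2af1) and 0 falling, against a median of -0.69 for the constant and joining-chain genes. This neither meets nor excludes the explanation, since abundant markers such as Txndc5 (201 CPM in vehicle libraries) and Xbp1 (139 CPM) are secretory genes that HSPCs also express and would hide a small share of plasma cells, and Xbp1, Derl3, Herpud1 and Creld2 also belong to the ER stress list.

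The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 2544 genes, and the highest of the other 9 called 1. Each of those 9 has vehicle and uridine libraries in both arms, so a group difference of any origin would itself lower its calls. The contrast therefore decides nothing about chance or about the source of the difference.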
